A study of Caenorhabditis elegans with 8 samples.

How the data were processed

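RNA of 8 samples of Caenorhabditis elegans was labelled with Cy3 and hybridised to 8 single-colour Agilent arrays, with 0.2 µg of labelled total RNA per sample. Per the file headers, the intensity values were extracted from the scans with Agilent Feature Extraction (10.7.1.1 in the submitters' notes), and the processed intensity of each spot is background-subtracted and detrended within its array, with no scaling between arrays. The deposited value table holds log2 values: recomputing the log2 of the processed intensity, minus the 75th percentile of the array, minus the mean of the 2 wild-type arrays of the same stage, gave all values of the 43603 shared probes within 0.01. No label states these steps, and since the table is centred within each stage it cannot give a comparison of stages.

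The log2 processed intensities were averaged over the spots of a probe, with control spots and spots flagged as outliers left out (between 4 and 12 flagged spots per array, 0 saturated), and the 75th percentile of each array was subtracted. The array design names an older genome build than the reference at hand, so no positions are given, and probes were named through the sequence name or transcript accession in the array files. This named 31500 probes by sequence name and 3674 by transcript accession and left 8429 unnamed and unused. Of 20008 named genes 16829 had a measured probe, meaning well above background on both arrays of at least 1 group, and 4992 had more than 1. The brightest measured probe stood for its gene. The array files hold no counts, and the number of arrays limits the precision.

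Groups followed the labels: genotype and stage, with 2 arrays in each of 4 groups. The labels do not say whether the replicates are separate cultures, so the p-values measure the spread between these samples. All 8 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 with its moderated test (4 residual and 2.39 prior degrees of freedom, two-sided), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Comparisons were knockout against wild type in embryos, the same in young adults, the difference between these effects, and wild-type embryos against wild-type adults. A gene was tested where its probe was well above background on both arrays of at least 1 of the groups compared. Where a called gene was at background on both arrays of a group, its fold is given as a bound against the lowest signal above background. The overlap of calls was tested with Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

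The genes named in the text follow a rule: seip-1; per genotype comparison the 10 largest rises and falls among called genes seen on at least 1 array of each group, with both knockout arrays beyond both wild-type arrays, and 2 per direction known by sequence name alone; up to 4 members per list by adjusted p; the 5 largest per direction for the interaction and the stages, among called genes with a gene name chosen in the same way; and called genes with the largest bounds. Genes in a count of 5 or fewer, the 15 adult calls and genes shared between stages were named after their values were seen.

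The 27 lists covered the eggshell and permeability barrier, yolk, fatty acid desaturases and elongases, fatty acid synthesis and its regulation, triglyceride and lipid droplets, lysosomal lipases, phospholipid synthesis, beta-oxidation, sphingolipids, endoplasmic reticulum stress, mitochondrial stress, heat shock, oxidative stress, osmotic stress, innate immunity, detoxification, cuticle collagens, sperm, oocyte and germline, early zygotic genes, late embryonic morphogenesis, muscle, intestine, neurons, replication-dependent histones, cell death with DNA damage, and autophagy. The symbols arf-1.2, vet-4 and opt-2 matched no gene. Each list was tested in both genotype comparisons with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 27 lists, and again with the correlation estimated and with fry, which tests whether the members move on balance in 1 direction. The main model, the gene lists, the naming rule and most alternatives were chosen before the data were examined.

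The procedure was tested on simulated data with the spread of these arrays and 200 changed genes per comparison. In embryos it recovered 32% of 2-fold, 78% of 4-fold and 90% of 8-fold changes, with 3 false calls of 104, and in adults 18%, 78% and 88%, with 1 false call of 93. Of 1.5-fold changes it recovered 2% in embryos and 0% in adults. In the embryo data 13065 genes passed, far more than the 200 changed here. The adjustment then lets through larger unadjusted p-values, so the shares for embryos do not describe that comparison. In the adult data 15 genes passed, fewer than the 93 calls here. The adjustment is stricter there, so the shares for adults are likely too high. The simulated arrays were also independent, with 1 spread per gene in all groups. Knockout adult arrays differed more than wild-type ones (standard deviation of the difference 0.66 against 0.445), so the false calls may be too few.

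Alternatives were quantile normalization, median scaling, the deposited value table, other filters on dim probes, a trended and robust prior, array weights, the mean of all probes of a gene, a replicate block, a slide block, fits of only the arrays compared, stricter thresholds, and leaving out each array in turn. Added after the data were seen were normexp background correction (offset 50) on median spot signals, in place of the planned one on mean spot signals, which the files do not hold, and a crossed block among the adults. With 2 arrays per group no other splits of the samples were counted.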

Results

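Gene expression was measured on 8 single-colour microarrays of Caenorhabditis elegans total RNA, from wild-type animals (N2) and from animals lacking seip-1, the worm's seipin gene, which encodes a lipid droplet protein of the endoplasmic reticulum. There were 4 groups of 2 arrays each: wild-type embryos, knockout embryos, wild-type young adults and knockout young adults. The adults were harvested 52 h after the L1 stage, and the embryos were taken from adults of that age. Of 43603 probes per array, between 65.7% and 75.5% were well above background, and the 75th percentile of the processed signal lay between 1387 and 2745. In embryos the signal differed by genotype before scaling. The median signal was 74.7 and 77.4 in wild-type and 265 and 214 in knockout embryos, with 65.7% and 66.6% against 75.5% and 71.9% of probes above background. In adults the median was 275 and 224 in wild type and 218 and 276 in the knockout. The standard deviation of the difference between the arrays of a group was 0.41 in wild-type embryos, 0.49 in knockout embryos, 0.44 in wild-type adults and 0.66 in knockout adults, on the log2 scale. With 2 arrays per group (n = 2 for every value below), the number of arrays limits the precision, and every ± is a standard error of the moderated linear model. The embryo arrays were all on 1 slide and the adult arrays all on another, so each genotype comparison lies within a slide, while stage and slide cannot be told apart.

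The targeted gene was compared first, as a check of the labels. The only probe of seip-1 (R01B10.6) read 3292 and 3871 intensity units in wild-type embryos and 5.19 and 6.72 in knockout embryos. In adults it read 3120 and 2966 in wild type against 5.74 and 6.97 in the knockout. No knockout array was above background for seip-1, so its level was at least 311-fold lower in embryos (adjusted p = 2.25e-05) and at least 114-fold lower in adults (adjusted p = 4.07e-05).

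The study's title places its question at eggshell formation, and the embryo comparison asks which transcripts differ in embryos without seipin. Knockout embryos held less RNA of germline and early embryonic genes and more RNA of differentiated tissues: all 36 oocyte and germline markers fell, while 22 of 23 muscle genes and 29 of 32 neuron markers rose. The calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.651 for each), and most genes of any kind passed the test. Among genes with a gene name that were seen in both groups, the largest falls were in the T-box transcription factor gene tbx-30, at 9.85-fold lower (log2 -3.30 ± 0.19), the histone gene his-47 (-3.24 ± 0.20) and the T-box gene tbx-40 (-3.24 ± 0.27). The largest rises among these genes were in bah-1, at 32.6-fold higher (log2 5.03 ± 0.42), and in the nuclear hormone receptors nhr-73 and nhr-245, at 32.1-fold (5.0 ± 0.15) and 30.2-fold (4.92 ± 0.16). Of 15394 genes tested, 13065 passed the test, 6862 upward and 6203 downward, and 10604 of them changed at least 2-fold. Which direction is the more frequent depends on the processing. It was 6348 upward against 6965 downward with median scaling, 5706 against 6507 with normexp correction and 4970 against 5554 with only probes above background on all arrays. With quantile normalization it was 6321 against 6208.

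Further genes with large rises were of several kinds. The cytochrome P450 cyp-35A3 rose by 4.40 ± 0.22 on the log2 scale, the cuticle collagen dpy-13 by 4.00 ± 0.66, the carboxylesterase cest-9.2 by 3.95 ± 0.18 and the sugar transporter swt-1 by 3.86 ± 0.24. The nuclear hormone receptor nhr-113 rose by 4.48 ± 0.23, bah-2 by 3.95 ± 0.43 and cln-3.1, a relative of the human Batten disease gene, by 3.89 ± 0.22. Of genes known by sequence name alone, ZK1025.3 and ZK1025.5 rose by 5.58 ± 0.59 and 5.50 ± 0.49. The scavenger receptor gene scav-5 was at background in wild-type embryos and at least 23.5-fold higher in knockout embryos. In all, 1206 of the called genes were higher and 198 lower with 1 of the 2 groups at background, so their fold changes are lower bounds.

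Among the further large falls, tbx-36, tbx-32, tbx-35 and tbx-39 fell by between 3.15 and 3.06 on the log2 scale. The histone gene his-58 fell by 3.02 ± 0.19, sdz-1 by 3.1 ± 0.19 and med-2, a GATA factor that specifies endoderm and mesoderm, by 3.03 ± 0.17. Y75B12A.2 and T04D3.8, known by sequence name alone, fell by 3.75 ± 0.18 and 3.41 ± 0.21. T-box, histone, major sperm protein, yolk and small heat shock genes have close relatives, and cross-hybridisation between them was not measured.

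Lists of maternal and early embryonic genes fell in knockout embryos. All 36 oocyte and germline markers fell (adjusted p = 1.87e-09, and adjusted p = 0.651 with an estimated correlation), among them pgl-1, a P granule component (log2 -2.61 ± 0.16), and him-3, a protein of meiotic chromosome axes (-2.98 ± 0.20). Of 30 early zygotic genes 19 fell and 2 rose (adjusted p = 0.00138, and adjusted p = 0.651 with an estimated correlation), with pes-10 at -2.67 ± 0.21. Of 20 replication-dependent histone genes 17 fell and 2 rose (adjusted p = 0.00115, and adjusted p = 0.651 with an estimated correlation), with his-61 at -2.93 ± 0.20 and his-41 rising by 1.88 ± 0.13. Of 28 genes of programmed cell death, engulfment and DNA damage 23 fell and 1 rose (adjusted p = 3.96e-04, and adjusted p = 0.651 with an estimated correlation). They included the checkpoint gene hus-1 (-2.68 ± 0.21) and the engulfment receptor gene psr-1 (-1.75 ± 0.16). Adjusted over the list alone, 18 histone genes fell, and the other counts were as above. The early zygotic list lost its call when only probes above background on all arrays were kept (adjusted p = 0.355).

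Lists of differentiated tissues rose in knockout embryos. Of 23 muscle genes 22 rose and 0 fell (adjusted p = 1.10e-05, and adjusted p = 0.651 with an estimated correlation), among them the tropomyosin gene lev-11 (log2 3.14 ± 0.15) and the myosin light chain gene mlc-2 (2.80 ± 0.15). Of 32 neuron markers 29 rose and 2 fell (adjusted p = 9.75e-06, and adjusted p = 0.651 with an estimated correlation), with the cilium transport genes che-3 at 3.20 ± 0.15 and osm-6 at 2.82 ± 0.13. Of 26 intestine genes 23 rose and 3 fell (adjusted p = 3.19e-04, and adjusted p = 0.651 with an estimated correlation), with the metallothionein gene mtl-2 at 3.76 ± 0.19 and the aspartyl protease gene asp-2 at 3.08 ± 0.19. Of 39 cuticle collagen and collagen-processing genes 34 rose and 0 fell (adjusted p = 1.81e-04, and adjusted p = 0.651 with an estimated correlation), with dpy-3 at 2.47 ± 0.15 and dpy-10 at 2.13 ± 0.14. Of 26 genes of late embryonic morphogenesis 18 rose and 2 fell (adjusted p = 0.00991, and adjusted p = 0.651 with an estimated correlation), with unc-52, which encodes perlecan, at 3.02 ± 0.16 and the lipocalin-related lpr-1 at 2.95 ± 0.16. Adjusted over the list alone, 30 neuron markers rose, and the other counts were as above.

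The eggshell, triglyceride and phospholipid lists were called downward in knockout embryos. Of 24 genes of the eggshell and permeability barrier 18 fell and 1 rose (adjusted p = 0.00115, and adjusted p = 0.667 with an estimated correlation). Their median was -1.65 on the log2 scale, while that of the oocyte and germline list was -2.41, so a fall particular to eggshell genes is not shown. In adults 0 of 26 measured members passed (median 0.02, camera adjusted p = 0.595). The egg activation gene egg-3 fell by 2.62 ± 0.23 on the log2 scale and gna-2, an enzyme of the chitin precursor pathway, by 2.61 ± 0.26, while sqv-4, which encodes UDP-glucose dehydrogenase, rose by 1.98 ± 0.21. Of 19 triglyceride and lipid droplet genes 14 fell and 2 rose (adjusted p = 0.0141, and adjusted p = 0.651 with an estimated correlation), with the acyltransferase gene acl-6 at -1.82 ± 0.17, the lipid droplet dehydrogenase gene dhs-3 at 1.95 ± 0.19 and dgat-2, a diacylglycerol acyltransferase gene, at -0.63 ± 0.13. Of 21 phospholipid synthesis genes 12 fell and 3 rose (adjusted p = 0.0493, and adjusted p = 0.653 with an estimated correlation), with the phosphatidylserine synthase gene pssy-2 at -2.15 ± 0.19 and the choline kinase gene ckb-3 at 2.92 ± 0.26. The S-adenosylmethionine synthetase gene sams-1 was at background in wild-type embryos and at least 2.98-fold higher in the knockout. Adjusted over the list alone, these counts were the same. The triglyceride list lost its call under quantile normalization (adjusted p = 0.116), and the phospholipid list lost it there (adjusted p = 0.271), with a replicate block (adjusted p = 0.0506), with normexp correction, array weights, mean probes or the embryo arrays alone (adjusted p from 0.0506 to 0.0750) and without any 1 array other than knockout embryo array 2 (adjusted p from 0.0509 to 0.0570).

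Genes of stress and defence went in different directions in knockout embryos. Of 27 endoplasmic reticulum stress genes 16 fell and 3 rose (adjusted p = 0.0141, and adjusted p = 0.678 with an estimated correlation), with cdc-48.1, which encodes an ATPase that extracts proteins for degradation, at log2 -1.63 ± 0.17 and the transcription factor gene atf-4 at 2.24 ± 0.17. Of 31 innate immunity genes 23 rose and 4 fell (adjusted p = 0.0141, and adjusted p = 0.667 with an estimated correlation), with the saposin-like spp-8 at 3.78 ± 0.22 and the lysozyme gene lys-8 at 3.02 ± 0.18. Of 29 detoxification genes 18 rose and 4 fell (adjusted p = 0.0277, and adjusted p = 0.653 with an estimated correlation), with ugt-22, a UDP-glucuronosyltransferase gene, at 3.63 ± 0.22. Adjusted over the list alone, these counts were the same. Under quantile normalization the stress list (adjusted p = 0.271) and the detoxification list (adjusted p = 0.0992) lost their calls, and the detoxification list did too without wild-type embryo array 2 (adjusted p = 0.0534) and with normexp correction (adjusted p = 0.0536).

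Of the 27 lists 15 passed the test in embryos, 7 upward and 8 downward, and 0 passed with an estimated correlation, where adjusted p ranged from 0.651 to 0.836. Late morphogenesis lost its call there at an estimated correlation of 0.048. In adults the lysosomal lipases lost theirs at -0.187 (camera p from 0.00248 to 0.0362). A call lost in this way is therefore no sign by itself that members vary together. The estimates themselves, however, ran from 0.048 to 0.859 over the 15 lists called in embryos, against the preset 0.01. They were 0.859 for oocyte and germline, 0.824 for eggshell, 0.654 for neurons and 0.575 for muscle. Members of such lists did vary together between the arrays of a group, and their adjusted p at the preset correlation may be far too small. Quantile and median scaling moved the embryo effects of single genes by a median of -0.39 and -0.29 on the log2 scale, and the median of all effects went from 0.15 to 0.02 and -0.15. With them 86% and 96.1% of the called genes kept call and direction. The balance between rises and falls thus depends on the scaling and on the other choices given above, while the medians of all 15 lists kept their sign under both scalings. A fit of the embryo arrays alone, all from 1 slide, called 13172 genes. Of the called genes 87.6% lay farther from wild type in knockout embryo array 1 than in array 2.

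**Figure D1:**
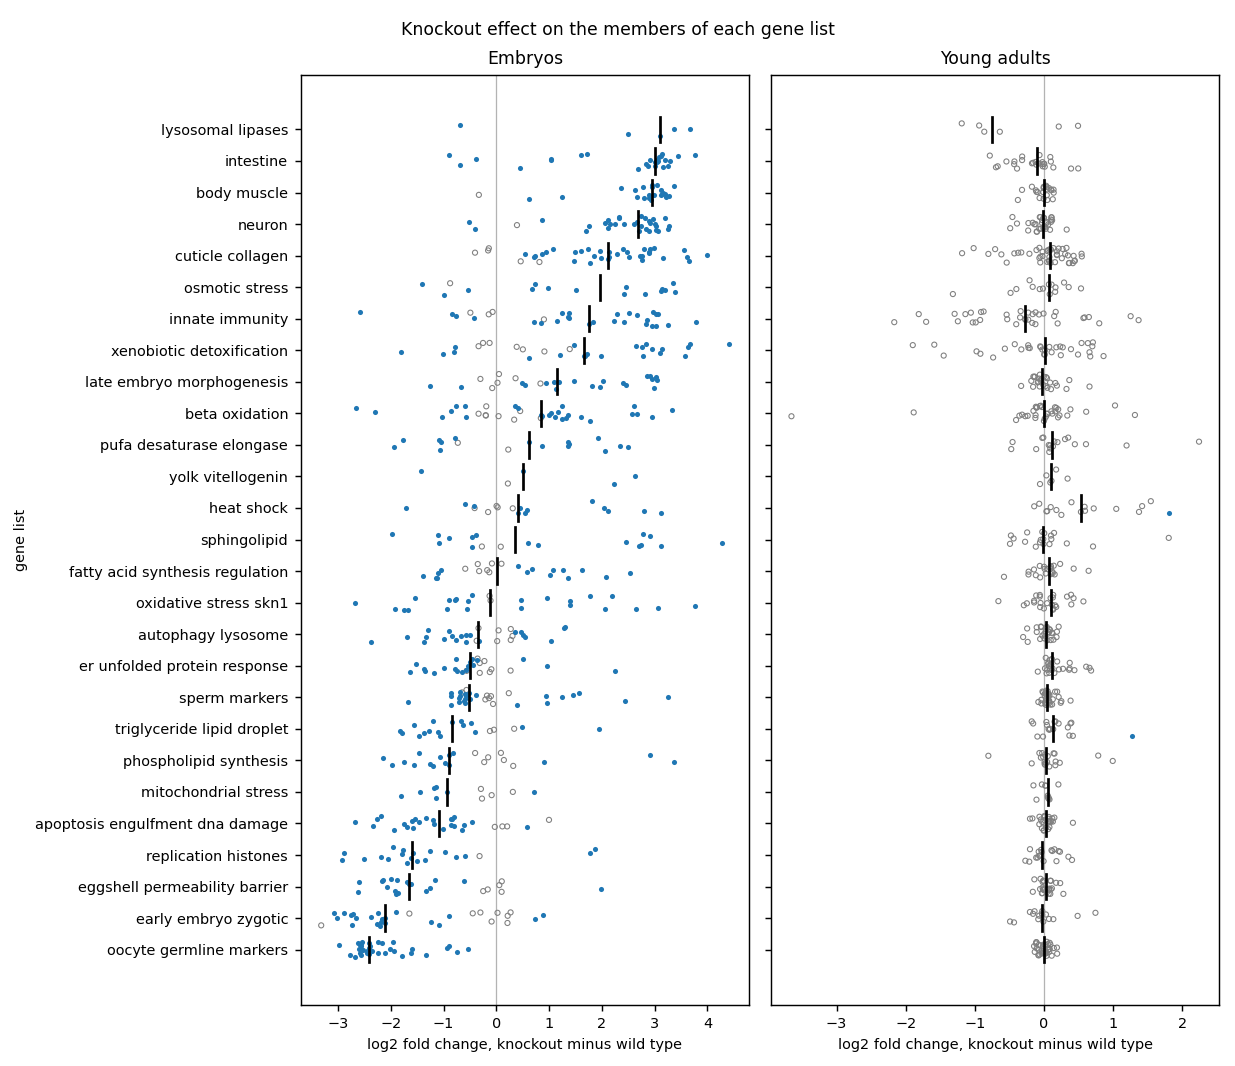
Log2 fold change, knockout minus wild type, of the measured members of each of the 27 gene lists in embryos (left) and young adults (right), with 2 arrays per group. Filled points passed adjusted p 0.05 over all genes, open points did not, the vertical position within a list is arbitrary and black bars are list medians, which run from -2.41 (oocyte and germline markers) to 3.11 (lysosomal lipases) in embryos and from -0.75 (lysosomal lipases) to 0.53 (heat shock) in adults.

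The adult comparison asks the same of young adults. Knockout adults differed from wild type in few genes: 10 rose and 5 fell of 15005 tested, and 789 had an unadjusted p under 0.05. The latter number is close to what this threshold lets through by chance among so many genes. Which direction is the more frequent depends on the processing: 22 rose and 30 fell with normexp correction, and 15 rose and 9 fell with a trended and robust prior. The small heat shock gene hsp-16.2 rose 3.49-fold (log2 1.80 ± 0.16), the potassium channel gene twk-13 rose 5.63-fold (2.49 ± 0.17), dod-3 rose 4.1-fold (2.04 ± 0.18) and dgat-2, which encodes a diacylglycerol acyltransferase of triglyceride synthesis, rose 2.41-fold (1.27 ± 0.13). With a replicate block hsp-16.2, dod-3 and dgat-2 lost their calls (limma adjusted p = 0.114, 0.114 and 0.217), and dgat-2 lost its call with the crossed block too (adjusted p = 0.0528). The lactamase-domain gene lact-6 and the short-chain dehydrogenase gene dhs-16 were at background in wild-type adults and at least 10.4-fold and at least 3.73-fold higher in the knockout. Besides seip-1, Y38H8A.1 fell 4.89-fold (log2 -2.29 ± 0.24), the MATH-domain gene math-45 fell 4.78-fold (-2.26 ± 0.19), and F58E6.8 was at background in knockout adults and at least 3.53-fold lower by its brightest probe.

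Of the remaining calls in adults, F36H1.12 was at least 2.44-fold higher and the chemoreceptor gene sri-57 at least 1.31-fold higher in the knockout, each against background in wild-type adults. F07C3.9 rose by 1.56 ± 0.15 on the log2 scale and the chemoreceptor gene srt-14 by 1.54 ± 0.13. C52E2.5 was at background in the knockout and at least 1.73-fold lower. Both knockout arrays lay beyond both wild-type arrays for each of the 15 genes. The other 3 probes of F58E6.8 gave -0.31, -0.05 and -0.05 where the brightest gave -4.06, while the other 2 probes of twk-13 gave 2.50 and 2.49. Of the 14 called genes other than seip-1, 8 lie on the chromosome that carries seip-1.

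The number of adult calls depends on the arrays in the fit. A fit of the 4 adult arrays alone, all from 1 slide, called 1 gene, seip-1, and a replicate block left 5. Without wild-type embryo array 1 or 2 there were 3 calls each, without knockout embryo array 1 or 2 there were 5 each, without wild-type adult array 2 there were 7, and without knockout adult array 1 or 2 there were 100 and 54. Without wild-type adult array 1 there were 17, of which 4 were among the 15 genes. The genes seip-1, dhs-16 and F58E6.8 kept their calls in each of the 8 fits that leave out 1 array, and the other 12 lost theirs in at least 1.

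**Figure D2:**
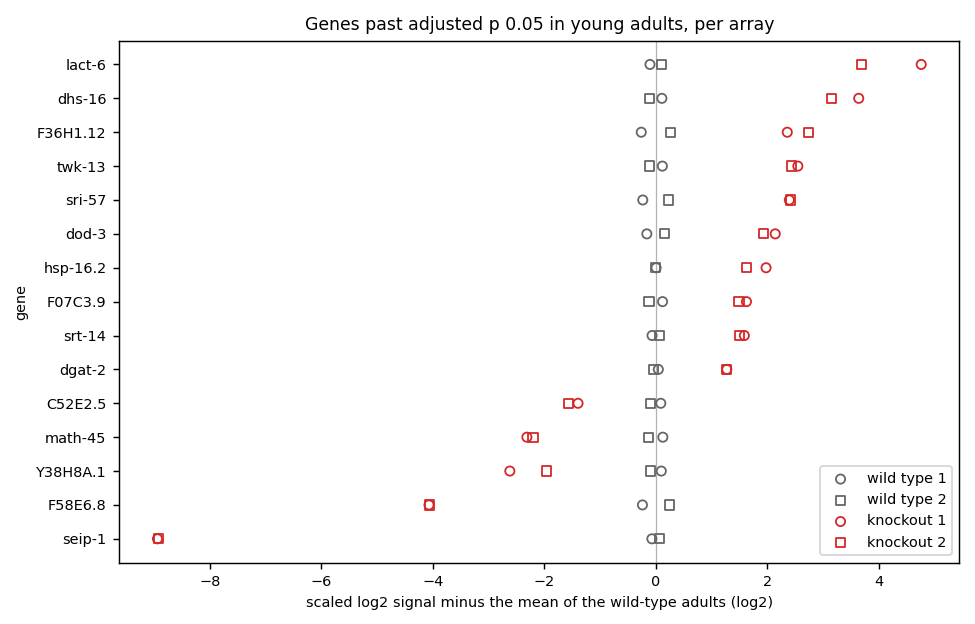
Scaled log2 signal of the 15 genes called in young adults, on each of the 4 adult arrays, relative to the mean of the 2 wild-type arrays of the gene. Circles and squares are arrays 1 and 2 of wild type (grey) and knockout (red), and the mean differences run from -8.93 for seip-1 to 4.22 for lact-6, both values against background and no measured fold.

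Cytosolic heat shock genes were higher in knockout adults as a group. Of 17 measured members 1 rose over all genes tested, and 9 rose adjusted over the list alone (adjusted p = 7.00e-17 for the list). The call was lost with an estimated correlation, which was 0.068 (adjusted p = 0.0768), and kept with fry (adjusted p = 0.00517). Beside hsp-16.2, the values were 1.54 ± 0.18 for hsp-16.41, 1.37 ± 0.18 for hsp-16.1 and 1.42 ± 0.19 for hsp-16.48 on the log2 scale, each short of the test over all genes. In 13 of the 17 members both knockout arrays lay above both wild-type arrays. Some of these margins were very small. The lower knockout array read 6.472 against 6.463 in the higher wild-type array for hsp-90, and 3.459 against 3.438 for hsp-25. How many genes of any kind separate in this way was not counted.

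**Figure D3:**
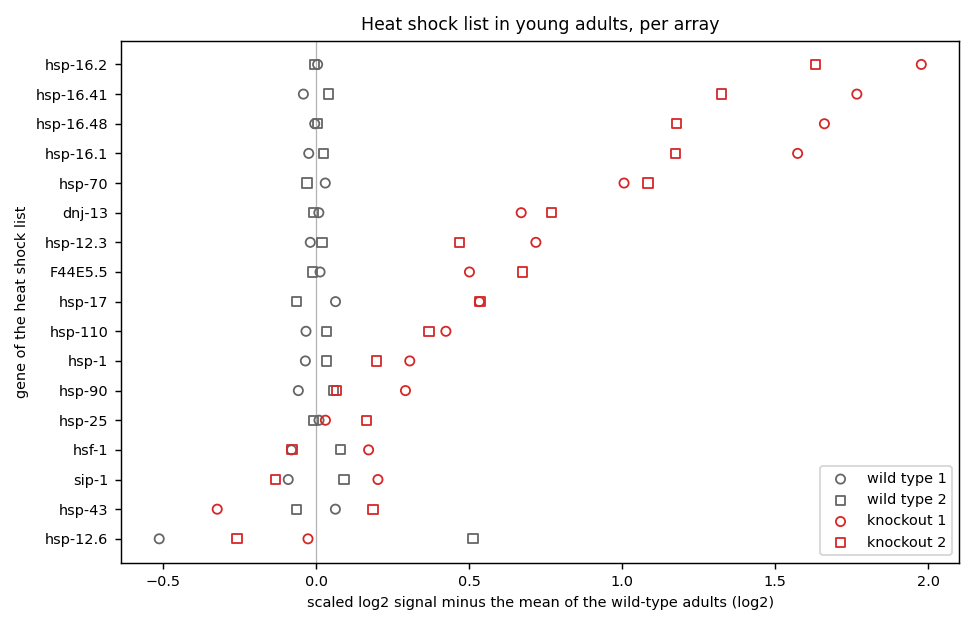
Scaled log2 signal of the 17 measured members of the heat shock list on each of the 4 young adult arrays, relative to the mean of the 2 wild-type arrays of the gene. Circles and squares are arrays 1 and 2 of wild type (grey) and knockout (red); hsp-16.2 has the largest mean difference, 1.80, and hsp-12.6 the lowest, -0.14.

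The lists of endoplasmic reticulum stress, of triglycerides and lipid droplets and of fatty acid desaturases and elongases were also called upward in adults. Of 27 endoplasmic reticulum stress genes 0 passed over all genes tested and 3 rose adjusted over the list alone (adjusted p = 1.62e-06, and adjusted p = 0.996 with an estimated correlation), with the chaperone gene hsp-4 at log2 0.68 ± 0.13, the transcription factor gene xbp-1 at 0.66 ± 0.13 and the kinase gene pek-1 at 0.61 ± 0.13. Of 19 triglyceride and lipid droplet genes 1, dgat-2, rose over all genes and adjusted over the list alone (adjusted p = 7.60e-04, and adjusted p = 0.996 with an estimated correlation), with dhs-9 at 0.42 ± 0.19 and abhd-5.2 at 0.37 ± 0.15. Of 18 fatty acid desaturase and elongase genes 0 passed over all genes and 1 rose adjusted over the list alone (adjusted p = 0.00851, and adjusted p = 0.503 with an estimated correlation), with the desaturase genes fat-5 at 2.24 ± 0.32 and fat-3 at 0.45 ± 0.15. Without knockout adult array 1 the calls of these 3 lists ended (adjusted p = 0.177, 0.365 and 0.126 in that order), and without knockout adult array 2 that of the desaturase list did (adjusted p = 0.0570).

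Called downward in adults were the lysosomal lipases and innate immunity. Of 6 measured lipases 0 passed over all genes and 2 fell adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.489 with an estimated correlation), with lipl-5 at log2 -1.19 ± 0.20 and lipl-2 at -0.86 ± 0.15. Of 36 innate immunity genes 0 passed over all genes, and 10 fell and 5 rose adjusted over the list alone (adjusted p = 0.00115, and adjusted p = 0.996 with an estimated correlation), with the C-type lectin genes clec-4 at -2.17 ± 0.45 and clec-66 at -1.71 ± 0.31 and dod-22 at -1.81 ± 0.32. Without knockout adult array 1 both calls ended (adjusted p = 0.141 and 0.365 in that order), and a fit of the adult arrays alone ended that of the lipases (adjusted p = 0.0639). The intestine list, not called (adjusted p = 0.0645), had 18 of 26 members below 0 and passed downward in some alternatives, among them quantile normalization (adjusted p = 0.0295). Of the 27 lists 6 passed in adults, 0 with an estimated correlation, 2 with fry (lysosomal lipases and heat shock) and 10 without knockout adult array 2.

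The interaction asks whether the knockout effect differs between embryos and young adults. Among genes with a gene name that were seen on at least 1 array of each of the 4 groups, those with the largest positive difference rose in knockout embryos, while their adult values did not pass the test. The difference was 5.73 ± 1.25 on the log2 scale for bath-26, 5.64 ± 0.97 for bath-47, 5.21 ± 0.69 for the acyl-CoA oxidase gene acox-1.5, 5.13 ± 0.64 for clec-4 and 5.07 ± 0.59 for bah-1. Adult falls short of the test were part of some of these values. For acox-1.5 the embryo effect was 3.33 and the adult effect -1.885, and clec-4 was lower in knockout adults too. For bah-1 nearly all of the difference was the embryo rise. The largest negative differences among these genes were in cpt-3, of the carnitine palmitoyltransferase family (-3.69 ± 0.41), the collagen gene col-78 (-3.65 ± 0.25), the histone gene his-47 (-3.32 ± 0.28), the endoderm factor gene end-3 (-3.22 ± 0.48) and sdz-37 (-3.19 ± 0.96). Of 16829 genes tested 12221 passed, 6566 with a more positive effect in embryos and 5655 with a more negative one. Which direction is the more frequent depends on the processing: it was 5963 against 6660 with median scaling, 5315 against 6133 with normexp correction, 4692 against 5179 with only probes above background on all arrays and 5675 against 5679 with quantile normalization. The call of sdz-37 was lost without wild-type embryo array 1 or 2, knockout embryo array 1 or 2 or wild-type adult array 1 (adjusted p from 0.0506 to 0.0736).

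Wild-type embryos and wild-type young adults were compared to describe where genes are expressed. Higher in embryos were the C-type lectin genes clec-266 (log2 11.65 ± 0.78) and clec-196 (11.16 ± 0.33), the cuticle collagen gene dpy-14 (11.32 ± 0.19), pes-2.1 (9.85 ± 0.45) and hil-7, a linker histone gene (9.82 ± 0.37). Lower in embryos were the collagen genes col-129 (-13.18 ± 0.15), col-124 (-12.63 ± 0.18), col-181 (-12.56 ± 0.46) and col-179 (-12.43 ± 0.25) and the yolk protein gene vit-2 (-12.41 ± 0.19). Of 16117 genes tested 13536 passed, 6670 higher and 6866 lower in embryos. Since each stage had a slide of its own, no value within a slide can be had, and quantile normalization moved the stage differences of single genes by a median of 0.36 on the log2 scale.

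The calls of the 2 genotype comparisons were set against each other over the 13570 genes tested in both. The genes dhs-16, dod-3, F07C3.9, hsp-16.2 and twk-13 rose in both stages, 5 where 3.48 were expected by chance, and F58E6.8, math-45 and seip-1 fell in both, 3 where 2.08 were expected. In opposite directions, C52E2.5 and Y38H8A.1 rose in embryos and fell in adults (2.18 expected), and dgat-2 and sri-57 fell in embryos and rose in adults (3.32 expected). None of these 4 overlaps differed from chance (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p from 0.874 to 1.00). The embryo call of hsp-16.2 (log2 0.41 ± 0.16) was lost without any of the 4 embryo arrays or either wild-type adult array (adjusted p from 0.0841 to 0.203), and with median scaling (log2 0.12, adjusted p = 0.480), no filter on dim probes (adjusted p = 0.0643), a replicate block (adjusted p = 0.0719) or the embryo arrays alone (adjusted p = 0.0592).

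At an unadjusted p under 0.01 in both stages, genes that rose in embryos and fell in adults were more frequent than expected for independent genes. Genes that fell in embryos and changed in either direction in adults were less frequent. Genes share the same arrays and are not independent, so the p-values of the exact tests below may be too small. In adults 114 genes rose and 132 fell at this threshold, of 13570, and part of them can be chance passes. There, 98 genes rose in embryos and fell in adults, acox-1.5 among them, where 53.3 were expected (Fisher's exact test, two-sided, p = 2.81e-15, adjusted p = 1.12e-14), and 13 fell in both, where 49.2 were expected (p = 1.15e-12, adjusted p = 2.30e-12). The 49 genes that rose in both compare with 46.0 expected (the same exact test, p = 0.567, adjusted p = 0.567), and the 19 that fell in embryos and rose in adults, hsp-4 and pek-1 among them, compare with 42.5 (p = 2.08e-06, adjusted p = 2.77e-06). Across the 13570 genes, which are not independent replicates, the log2 fold changes of the 2 stages had a Pearson r of -0.19 and a Spearman rho of -0.23. The 8 calls shared in direction became 3 without wild-type embryo array 1 or 2, 5 without knockout embryo array 1 or 2 or wild-type adult array 2, 27 without knockout adult array 1, 22 without knockout adult array 2, and 1 in fits of each stage alone.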

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

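In this part, the tests of embryo age, of sperm marker levels, of array scaling, of the chromosome share and of members varying together were chosen after the results were seen, and the tests of adult tissue by the share of risen genes, of linkage, of single probes and of leaving out an array were written before.

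In embryos 13065 genes passed the test, with falls in germline and early embryonic genes and rises in genes of differentiated tissues. Adult tissue left in the knockout preparations is argued against as the whole cause, since 49.1% of the risen genes (3371 of 6862) lay more than 1 log2 unit above both adult groups. Besides, 23 sperm markers abundant in adults (median 6.00 there) had medians of -3.49 in wild-type and -4.09 in knockout embryos, with 0 higher by over 1. Of the 5 measured members of the yolk list, however, 3 rose, all of them yolk protein genes, with vit-1 and vit-2 at log2 2.63 and 2.24. The 1 that fell was rme-2, the gene of the oocyte receptor. A part from adult tissue therefore stays open. The choice of scaling is argued against as the whole cause, since at least 86% of the called genes kept call and direction under quantile and median scaling. A candidate explanation is that the knockout preparations held older embryos: the difference between the knockout arrays ran along the knockout effect (Pearson r = 0.729 across 13065 genes, which are not independent, against 0.168 for the difference between the wild-type arrays), and 87.6% of the called genes lay farther from wild type in knockout array 1, with medians of 2.61 against 2.22 for risen and -1.54 against -1.29 for fallen genes. An effect of the knockout that differs in size between preparations would give the same correlation, and whether genotype changed the age or survival of the embryos or the harvest did so was not tested. Knockout embryo array 1 was also brighter before scaling than array 2 (median signal 265 against 214), and the wild-type embryo arrays were dimmer than both (74.7 and 77.4). Whether signal strength contributes was not tested.

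In young adults 14 genes other than seip-1 passed the test. Close linkage to the seip-1 locus is argued against as the cause of most of these calls, since a share of 0.071 of them (1 of 14, dhs-16) was among the 500 nearest protein-coding genes of its chromosome, while for dhs-16 itself it stays open (0.333 genes were expected there by chance). Differences of strain background along that chromosome may contribute: it carried 8 of the 14 genes, and 39.9% of the genes at an unadjusted p under 0.01 (n = 283 genes) against 20.4% of those tested (Fisher's exact test, two-sided, p = 3.89e-14), a ratio of 1.96 against 0.47 to 0.98 for the other chromosomes, and 38.3% under quantile normalization. Among the 500 nearest genes lay 9 of the 283 (3.2%), against 2.4% of those tested, so most of the excess lay farther from the locus. Genes of the 283 on that chromosome went the same way in embryos in 41 of 90 cases (45.6%). Elsewhere 44 of 155 (28.4%) did (Fisher's exact test, two-sided, p = 0.00813). Those on the chromosome did not do so more often than not, which is no support by itself. As neighbouring genes come in families and are not independent, both p-values may be too small. Sequence variants under single probes remain open, since only 2 of the called genes had another measured probe and a share of 0.5 (1 of 2) moved with it, and a direct effect of the knockout on these genes was not tested apart from strain.

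The heat shock list was higher in knockout adults. A single array as its source is argued against, since the list kept its call without each of the 4 adult arrays in turn (adjusted p from 6.84e-14 to 6.70e-08, mean effect from 0.55 to 0.68). Whether members that vary together between arrays account for the call stays open. It ended when that correlation was estimated, at 0.068 (camera p = 0.00285, adjusted p = 0.0768), but the list kept its call with fry (adjusted p = 0.00517). The lost call therefore does not decide the question, and the mean effect stayed the same by construction. The knockout itself and a difference in handling between cultures both remain open, as neither was tested.

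The knockout effect differed between embryos and young adults by a test of the difference itself in 12221 of 16829 genes. It did so in all but 3 of the 116 named genes too. These were chosen largely for their effects or p-values in 1 stage or for the interaction, so that count is no separate support. The values that follow are the embryo effect minus the adult effect on the log2 scale. Where a group was at background they are fitted values and no bounds. Among the genes with the largest embryo rises, the difference was 5.07 for bah-1, 4.81 for nhr-73, 4.67 for nhr-245, 3.76 for nhr-113, 4.01 for cyp-35A3, 4.37 for dpy-13, 4.21 for bah-2, 3.83 for cest-9.2, 4.15 for cln-3.1, 3.73 for swt-1, 5.85 for ZK1025.3, 5.78 for ZK1025.5 and 6.98 for scav-5. Among those with the largest embryo falls it was -3.24 for tbx-30, -3.32 for his-47, -3.46 for tbx-40, -3.09 for tbx-36, -3.06 for tbx-32, -3.06 for sdz-1, -3.02 for tbx-35, -3.0 for tbx-39, -1.94 for med-2, -3.02 for his-58, -3.68 for Y75B12A.2 and -3.2 for T04D3.8. For germline, early embryonic and cell death genes it was -2.65 for pgl-1, -2.95 for him-3, -2.6 for pes-10, -3.11 for his-61, 1.47 for his-41, -2.72 for hus-1, -1.9 for psr-1, -3.22 for end-3 and -3.19 for sdz-37. For eggshell and lipid genes it was -2.62 for egg-3, -2.59 for gna-2, 2.01 for sqv-4, 2.17 for elo-9, -2.04 for elo-1, -2.07 for fat-1, 1.75 for fat-6, -1.37 for fat-5, -1.72 for acl-6, 1.56 for dhs-3, -1.9 for dgat-2, -0.77 for abhd-5.2, -1.26 for dhs-9, -2.19 for pssy-2, 1.92 for ckb-3, 4.17 for sams-1, 4.23 for lipl-2, 4.87 for lipl-5, 2.69 for acdh-1, 3.36 for ech-7, 5.21 for acox-1.5, -3.69 for cpt-3, 4.4 for cgt-2, 2.9 for sptl-2, 2.11 for acs-1 and 2.19 for acs-17. For muscle, neuron, intestine, cuticle and morphogenesis genes it was 3.09 for lev-11, 2.77 for mlc-2, 3.3 for che-3, 3.21 for osm-6, 3.87 for mtl-2, 3.1 for asp-2, 2.11 for dpy-3, 2.18 for dpy-10, -3.65 for col-78, 3.0 for unc-52 and 3.02 for lpr-1. For stress and defence genes it was 1.88 for atf-4, -1.66 for cdc-48.1, -1.43 for hsp-4, -1.1 for pek-1, -1.87 for ubl-5, -1.49 for lonp-1, 2.71 for hsp-25, 3.18 for hsp-43, -1.39 for hsp-16.2, -1.7 for hsp-16.41, -1.37 for hsp-16.1, -1.83 for hsp-16.48, -3.02 for gst-30, 3.02 for hmit-1.3, 3.15 for osm-11, 4.01 for spp-8, 3.29 for lys-8, 2.65 for dod-22, 4.95 for clec-66, 5.13 for clec-4 and 3.55 for ugt-22. For yolk, autophagy and sperm genes it was 2.13 for vit-2, 2.29 for vit-1, -1.37 for rme-2, 1.53 for hlh-30, -1.18 for lmp-1, 3.21 for spe-10 and 2.35 for ssp-10. For the other genes called in adults it was -4.82 for lact-6, -1.0 for dhs-16, -2.88 for F36H1.12, 1.0 for twk-13, -3.64 for sri-57, 0.71 for dod-3, -3.68 for srt-14, 1.43 for F58E6.8, 4.08 for Y38H8A.1, 0.9 for math-45 and 4.45 for C52E2.5. For the remaining genes named for their interaction it was 5.73 for bath-26 and 5.64 for bath-47. For seip-1 the difference was -0.91 with knockout arrays at background in both stages, so it orders nothing. For tbx-30, tbx-40, tbx-32, tbx-35, tbx-39, sdz-1, pes-10 and Y75B12A.2 both adult groups were at background. They were so for med-2 too, where background values that differ by -1.08 between the adult groups enter the difference, so its size is not to be read.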

How the results depend on the processing

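In this part, normexp correction and the crossed block were chosen after the data were seen. The adult count of 15 genes is the least stable result: it was 52 with normexp correction on median spot signals, 24 with a trended and robust prior, 8 with array weights, 5 with a replicate block, 1 with only the adult arrays and 3 at adjusted p under 0.01, and ranged from 3 to 100 when 1 array was left out, the lone array of a group being assumed to vary like the other groups. The cause was not tested. Counts close to 15 did not always hold the same genes: the crossed block called 16 with 11 of the 15 kept (dgat-2, F07C3.9, C52E2.5 and F36H1.12 were lost), no filter 13 with 10 kept, only probes above background on all arrays 14 with 7 kept (the other 8 genes, seip-1 among them, did not pass that filter), quantile normalization 12 with 12 kept, median scaling 14 with 14 kept, and mean probes 16 with 14 kept, while the values deposited with the series gave all 15 and no others. The 8 calls shared in direction between stages became 5 with only probes above background on all arrays, 4 with a replicate block, 1 with only the arrays compared and 62 at an unadjusted p under 0.01, and ranged from 3 to 27 when 1 array was left out, and the cause was not tested. The 15 lists called in embryos became 0 with an estimated correlation and 24 with fry, and ranged from 13 to 15 when 1 array was left out. The 6 lists called in adults became 0 and 2 in the same order, and ranged from 4 to 10. The test with an estimated correlation asks the same question as the main test, while fry asks a different one by construction. The oocyte and germline list in adults, not called at adjusted p = 0.859, was called downward without knockout adult array 1 (adjusted p = 0.0119) and upward without knockout adult array 2 (adjusted p = 0.0155), with adjusted p between 0.0119 and 0.836 over the left-out arrays, and the cause was not tested.

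Counts in embryos ranged from 10524 to 13666 over the alternatives and from 11897 to 13291 over the left-out arrays, those of the interaction from 9673 to 12623 and 10642 to 12517, and those between stages from 10027 to 14209 and 12273 to 13704. Of 83 named embryo genes 81 kept direction and side of the threshold in each alternative in which they were tested, of 29 adult genes 9, of 10 interaction genes 9 and of 10 stage genes 10, and 0 reversed. Requiring probes above background on all arrays left part of these genes untested (64 of the 83 embryo genes remained). Signal over background limits the folds of dim genes, which are bounds where a group was at background, and the test on simulated data recovered few changes under 2-fold.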

Other observations

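In this part only the normexp correction was chosen after the data were seen, and nothing was tested as a cause. In knockout embryos the yolk protein genes vit-1 and vit-2 were higher (log2 2.63 ± 0.24 and 2.24 ± 0.19) and their oocyte receptor gene rme-2 was lower (-1.43 ± 0.27). Of the 5 measured members of the yolk list 3 rose and 1, rme-2, fell, as many adjusted over the list alone (adjusted p = 0.402). The list median of 0.50 became -0.43 under quantile normalization. Of 5 lysosomal lipases 4 rose and 1 fell (adjusted p = 0.134), with lipl-5 at 3.68 ± 0.20 and lipl-2 at 3.37 ± 0.15. Of 34 beta-oxidation genes 19 rose and 7 fell (adjusted p = 0.253), with the dehydrogenase gene acdh-1 at 2.66 ± 0.14 and ech-7 at 2.96 ± 0.19, and quantile normalization brought the list past the threshold (adjusted p = 0.0320). Of 18 sphingolipid genes 9 rose and 7 fell (adjusted p = 0.627), with the palmitoyltransferase gene sptl-2 at 2.46 ± 0.21 and the glucosyltransferase gene cgt-2 at least 11.6-fold higher than the background of wild-type embryos. Of 17 desaturase and elongase genes 9 rose and 6 fell (adjusted p = 0.774), with fat-6 at 2.35 ± 0.22, elo-9 at 2.06 ± 0.15, elo-1 at -1.95 ± 0.16 and fat-1 at -1.77 ± 0.16. Of 22 genes of fatty acid synthesis and its regulation 10 rose and 5 fell (adjusted p = 0.774), with acs-1 at 2.54 ± 0.20 and acs-17 at 2.08 ± 0.17, and the median of 0.01 became -0.29 under median scaling. Adjusted over the list alone, these counts were the same.

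Among the other lists without a call in embryos, 12 of 16 osmotic stress genes rose and 3 fell (adjusted p = 0.148), with osm-11 at log2 3.13 ± 0.23 and hmit-1.3 at 2.81 ± 0.20. Of 17 heat shock genes 9 rose and 3 fell, 8 and 3 adjusted over the list alone (adjusted p = 0.361), with hsp-25 at 2.80 ± 0.13 and hsp-43 at 3.12 ± 0.20, where 11 of 12 other probes went the same way. Of 25 oxidative stress genes 11 rose and 12 fell (adjusted p = 0.565), with gst-30 at -2.69 ± 0.14, a median of -0.13 that became 0.14 under quantile normalization, a mean of 0.22 and a test direction downward. Of 11 mitochondrial stress genes 6 fell and 1 rose (adjusted p = 0.0640), with ubl-5 at -1.81 ± 0.16 and the protease gene lonp-1 at -1.44 ± 0.13, and median scaling brought the list past the threshold (adjusted p = 0.0317). Of 28 autophagy and lysosome genes 14 fell and 7 rose (adjusted p = 0.236), with lmp-1 at -1.29 ± 0.15, the transcription factor gene hlh-30 at 1.3 ± 0.13 and a median of -0.36 that became 0.06 under quantile normalization. Of 32 sperm markers 16 fell and 8 rose (adjusted p = 0.236), with ssp-10 at 2.44 ± 0.27 and spe-10 at least 2.40-fold higher than the background of wild-type embryos, a call lost with normexp correction (log2 0.13, adjusted p = 0.616), and quantile normalization brought the list past the threshold downward (adjusted p = 0.00275). Counts adjusted over the list alone were the same except where given.

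In young adults the 21 lists without a call had adjusted p from 0.0645 for intestine to 0.987 for muscle, and 0 of their members rose or fell over all genes tested with limma. Adjusted over the list alone, 1 detoxification gene rose and 3 fell, and no other list of the 21 had a member past the threshold, nor did fry call any of them. The intestine list passed downward under quantile normalization (adjusted p = 0.0295), normexp correction (0.0432) and a trended and robust prior (0.0281), and without either knockout embryo array (0.0490) or knockout adult array 2 (0.0336). Other lists passed when 1 adult array was left out: eggshell without knockout array 2 (adjusted p = 0.0246) or wild-type array 2 (0.0321), cell death without the same arrays (0.0185 and 0.0321), cuticle collagens without knockout array 1 (9.12e-07) or wild-type array 1 (9.07e-05), sperm without these (0.00159 and 0.0158), and histones without knockout array 2 (0.0336). The oocyte and germline list passed without knockout array 1 (0.0119, downward), knockout array 2 (0.0155, upward) or wild-type array 2 (0.0283, upward). The adjusted p was 0.595 for eggshell, 0.321 for yolk, 0.627 for fatty acid synthesis, 0.227 for phospholipid synthesis, 0.859 for beta-oxidation, 0.958 for sphingolipids, 0.627 for mitochondrial stress, 0.244 for oxidative stress, 0.640 for osmotic stress, 0.969 for detoxification and 0.167 for cuticle collagens. It was 0.221 for sperm, 0.859 for oocyte and germline, 0.627 for early zygotic genes, 0.969 for late morphogenesis, 0.627 for neurons, 0.321 for histones, 0.419 for cell death and 0.640 for autophagy. The median and mean differed in sign for beta-oxidation (0.01 and -0.08), sphingolipids (-0.01 and 0.06), osmotic stress (0.07 and -0.06), detoxification (0.01 and -0.09), muscle (0.002 and -0.02), late morphogenesis (-0.02 and 0.02) and histones (-0.03 and 0.03).

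The differences between replicates 1 and 2 of wild type and knockout correlated across genes, which are not independent, with r = 0.002 in embryos and r = -0.477 in adults. Adult arrays of unlike number were thus alike: r was 0.991 for wild type 1 with knockout 2 and 0.990 for wild type 2 with knockout 1. It was 0.982 between the knockout arrays and 0.992 between the wild-type arrays. Cuticle collagen medians ran the same way, at 0.97 and 0.05 in wild type 1 and 2 and -0.04 and 1.07 in knockout 1 and 2. Leaving out 1 adult array shifts such lists.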
